A study of Homo sapiens with 2 samples.

How the data were processed

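HepG2, a human hepatoma cell line, was transfected on collagen-coated plates with a locked nucleic acid (LNA) oligonucleotide against TUC338, a noncoding transcript that contains an ultraconserved element, or with a control LNA. Per the labels' protocols, total RNA was isolated with Trizol, amplified and converted to cDNA with a whole-transcript kit, then fragmented and labelled with biotin. The groups were taken from the transfection label of each sample, which gave 1 array for the knockdown and 1 array for the control.

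The authors deposited 1 table with a value for each of 45200 probe sets on each of the 2 arrays. The probe annotation supplied with the table is that of an Affymetrix human exon array, on which a probe set covers roughly an exon, so most genes were measured several times on each array. The normalization, summary method, software and genome build are not given in the sources used here. The scale of the deposited values is also unstated and was settled from the numbers. The exponentials of the deposited natural log values under an intensity of 2000 fell far more often than at other residues on whole multiples of 0.5 plus 1 fixed residue. On the knockdown array 1154 of 41367 such values fell in the fullest residue bin of width 0.001, against a mean of 82.7 per bin, and on the control array 1167 of 42089 did, against a mean of 84.2. Read as log2 values, the fullest bins held 117 and 115 values against a mean of 90.4. The values were therefore treated as natural logs of intensity and divided by the natural log of 2 to give log2 intensities. A total of 1169 values occurred exactly on both arrays. Direction was taken from the sample labels.

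The annotation gave 1 gene symbol for 42575 probe sets, several symbols for 1055 and none for 1570. Only probe sets with 1 symbol were assigned to a gene. Of the 2795 symbols, 2449 were current in the RefSeq gene table of GRCh38.p14, 331 were updated from an older symbol, and 15 that are older names of several genes were kept as listed, which left 2792 genes with a median of 12 probe sets. The table thus holds a part of the genes of the genome, and the rule that chose them is not given in the sources used here. No coordinates were printed because the build of the probe sets is not known.

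Each gene was represented by its brightest probe set, the one with the highest mean over both arrays, and the difference was the knockdown log2 intensity minus the control log2 intensity. Genes entered the counts and lists when that mean was at or above the median over all genes, a log2 intensity of 10.22, which left 1396 genes. The mean, the SD and the number of probe sets of a gene were computed beside this value. These SDs measure how far the exons of a gene agreed between the same 2 arrays and do not replace replicate cultures. The difference over all genes had a median of 0.20 at the brightest probe set and 0.28 for the means over probe sets (log2), so single genes are given relative to the median gene on the matching scale unless called deposited values.

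With 1 array per condition no test was possible, and no p-value for a difference between conditions is given. Genes were counted at a difference of at least 2-fold. For 40 gene lists fixed before the data were examined, the median difference was placed among the medians of 10000 random lists of the same size, matched on mean intensity in 20 bins. A list with fewer than 5 genes at or above the floor was given no percentile, and lists above the 97.5th or below the 2.5th percentile were counted as standing apart in these 2 arrays. The genes named were also chosen by a rule set before the data were examined. They are the 15 largest increases and the 15 largest decreases at or above the floor, leaving out small RNAs and uncharacterised loci, with up to 4 members of each list and PCBP2.

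The procedure was tested on simulated data made from the measured intensities of the 1396 genes of this comparison, with a noise SD of 0.28 (log2). Simulated differences were counted relative to the median gene, so the shares below do not describe counts in deposited values. Of 50 genes simulated with a 3-fold change, 49 were counted at 2-fold or more. Of 50 genes with a 2-fold change, 20 were counted, and of 50 with a 1.5-fold change, 3 were. One of 1186 unchanged genes was counted. A list seeded with an increase of 0.5 (log2) reached the percentile 99.99, and 1 of the 15 other lists was called in a tail. The other lists could hold genes simulated as changed, so this is not a rate for unchanged lists. The largest list median found in the main setting was 0.23 relative to the median gene, so detection of shifts of that size was not tested. The simulated noise was that between probe sets of the same 2 arrays, so these shares leave out differences between cultures. Unchanged genes were also given no difference of their own, although the measured gene means spread with an SD of 0.30 over genes with at least 4 probe sets. Computations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

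The alternatives were no level floor, a floor at the 75th percentile, quantile normalization, median centring, subtraction of a loess curve (span 0.4), the mean over the probe sets of a gene, thresholds of 1.5-fold and 3-fold, random lists without matching, and list means. Median centring of the means over probe sets and removal of a trend with gene density were added after seeing the data. The design fixed before the data were examined assumed log2 or linear values. Since the deposited values were natural logs, they were converted and the planned comparison was kept. The number of arrays limits the precision.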

Results

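Whole-transcript expression was measured in HepG2 cells after transfection with an LNA oligonucleotide against TUC338 or with a control LNA, on 1 array per condition, so every difference below compares 2 arrays and has no replicate check. The median intensity over 45200 probe sets was 507 on the knockdown array and 422 on the control array, and the highest values were 19959 and 20261. Across probe sets the arrays correlated with a Pearson r of 0.950. The knockdown array was brighter for 71.0% of the 2792 genes, with a median difference of 0.20 on the log2 scale, or 1.15-fold. Probe sets of 1 gene differed from one another by an SD of 0.28 in their log2 difference, pooled over genes, and the gene means, over genes with at least 4 probe sets, by an SD of 0.30 from gene to gene.

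The first comparison concerned the targeted transcript and its host gene. No probe set in the table was annotated to TUC338 itself, so its level was not measured by a named probe set here. The design text states that the knockdown had been checked by experiment. In the RefSeq gene table TUC338 lies within PCBP2, which encodes poly(rC)-binding protein 2, an RNA-binding protein of mRNA stability and translation. PCBP2 was lower on the knockdown array at 12 of its 13 probe sets. At its brightest probe set the deposited log2 intensity was 11.40 in the knockdown and 12.28 in the control, a difference of -0.87. The mean over the 13 probe sets was -0.61 ± 0.35 (SD over probe sets) in deposited values, which is 65.5% of the control level, and -0.89 relative to the median gene, which is 53.8% of control. Of 2742 genes with at least 4 probe sets, 20 including PCBP2 had a mean as low or lower. The remaining probe set was 0.36 higher in deposited values. The positions of the 13 probe sets relative to TUC338 were not analysed here, so it is not known whether any of them overlaps TUC338, and PCBP2 was not used as a check of the knockdown label.

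**Figure D1:**
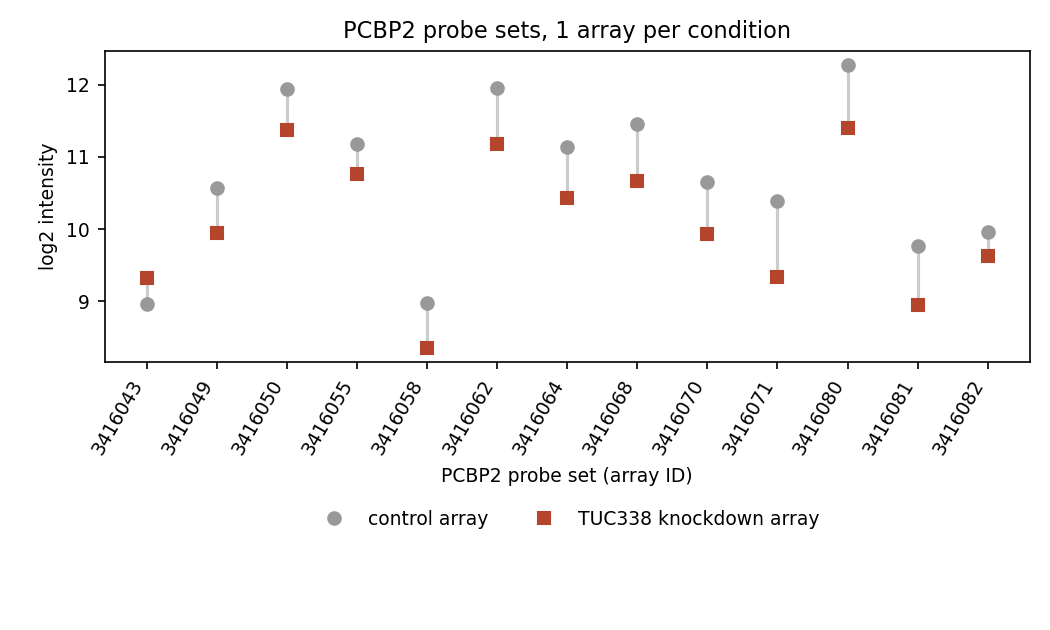
Log2 intensity (vertical axis) of each of the 13 PCBP2 probe sets (horizontal axis, by array identifier) on the control array (grey circles) and the TUC338 knockdown array (red squares), with a line joining the 2 arrays. The knockdown value lies below the control value at 12 of the 13 probe sets.

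The second comparison was of all genes between the knockdown and the control, the question posed by the title of the study. Of 1396 genes at or above the level floor, 17 were at least 2-fold higher and 4 at least 2-fold lower in deposited values. Because the median gene was itself higher, the split turned when the differences were taken relative to it, to 2 higher and 8 lower, so the share of higher genes went from 81.0% to 20%. The 2 higher genes were NCEH1, a neutral cholesterol ester hydrolase, and ZFAND1, a zinc-finger protein linked to stress granules. The 8 lower genes were TSC1, GOLGA2, PICK1, SLC38A10, TNRC6A, RNF213, DAB2 and PCBP2. Of these, TSC1, GOLGA2, PICK1 and SLC38A10 had means over probe sets near the median gene, as given below. By means over probe sets, 2 genes at or above the floor were at least 2-fold higher and 4 at least 2-fold lower relative to the median gene. No gene reached 3-fold in deposited values.

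Among the 15 genes with the largest increase, 12 had every probe set above the median gene and 11 had a mean over probe sets at least 1.5-fold higher. The brightest probe set, by which the genes were chosen, enters both counts, here and for the decreases below. The counts are therefore partly set by the choice. ZFAND1 was 2.26-fold higher, with a mean over 8 probe sets of 1.18 ± 0.15 (log2, SD over probe sets, here and below). IFRD1, a transcriptional co-regulator, had a mean of 1.0 ± 0.27 over 13 probe sets, and NCEH1 one of 0.96 ± 0.42 over 8. HSPA13, a member of the HSP70 chaperone family, was higher by 0.87 ± 0.20 over 8 probe sets. FOXQ1, a forkhead transcription factor, was higher by 0.83 ± 0.26 over 5 probe sets. GPAM, the mitochondrial acyltransferase that starts glycerolipid synthesis, was higher by 0.78 ± 0.15 over 24 probe sets. Smaller means were seen for the phosphatase CTDSP2 (0.69 ± 0.19), the adaptor CD2AP (0.65 ± 0.28), the autophagy receptor CALCOCO2 (0.64 ± 0.31), the plasma protein ITIH3 (0.64 ± 0.20), SDAD1 (0.64 ± 0.25) and the vesicle-trafficking subunit TRAPPC11 (0.56 ± 0.28). The brightest probe set overstated the rest of the gene for HNMT, which inactivates histamine (mean 0.44 ± 0.29), for the splicing regulator MBNL1 (0.43 ± 0.35) and for IBTK (0.16 ± 0.29).

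Among the 15 genes with the largest decrease, 8 had a mean over probe sets at least 1.5-fold lower and 4 had every probe set below the median gene. IGF2R, the receptor for insulin-like growth factor 2 and mannose-6-phosphate-tagged lysosomal enzymes, was lower at all of its 52 probe sets, with a mean of -1.13 ± 0.27, or 2.18-fold. TNRC6A, a scaffold of microRNA-guided silencing, was lower at 27 of 28 probe sets (mean -1.03 ± 0.41). The endocytic adaptor DAB2 was lower at all 17 (-0.98 ± 0.28). IL1R1, the interleukin-1 receptor, was lower at all 11 (-0.87 ± 0.44), and FRMD5 at all 17 (-0.75 ± 0.29). The ubiquitin ligase RNF213 was lower at 64 of 65 probe sets (-0.83 ± 0.28), and the laminin chain LAMA5 at 57 of 58 (-0.68 ± 0.25). PCBP2, described above, was the remaining gene of the 8.

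The other 7 of the 15 lower genes had means within 1.5-fold of the median gene, and their place rested on the brightest probe set. TSC1, a negative regulator of mTORC1, showed the largest single difference, -1.41 relative to the median gene, while its mean over 25 probe sets was -0.16 ± 0.40. The Golgi matrix gene GOLGA2 had -1.39 at its brightest probe set and a mean of -0.18 ± 0.46, and PICK1 had -1.33 and a mean of -0.17 ± 0.55. The means of SLC38A10 (-0.03 ± 0.42), ABCC10 (-0.13 ± 0.35), SERINC2 (-0.34 ± 0.42) and TRIO (-0.35 ± 0.27) were also small. TRIO lay below the median gene at 54 of 59 probe sets and SERINC2 at 34 of 41, so most of their probe sets shared the direction. SLC38A10 did so at 8 of 14 and ABCC10 at 8 of 17. In deposited values the means of TSC1, GOLGA2, PICK1, SLC38A10 and ABCC10 lay above 0.

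**Figure D2:**
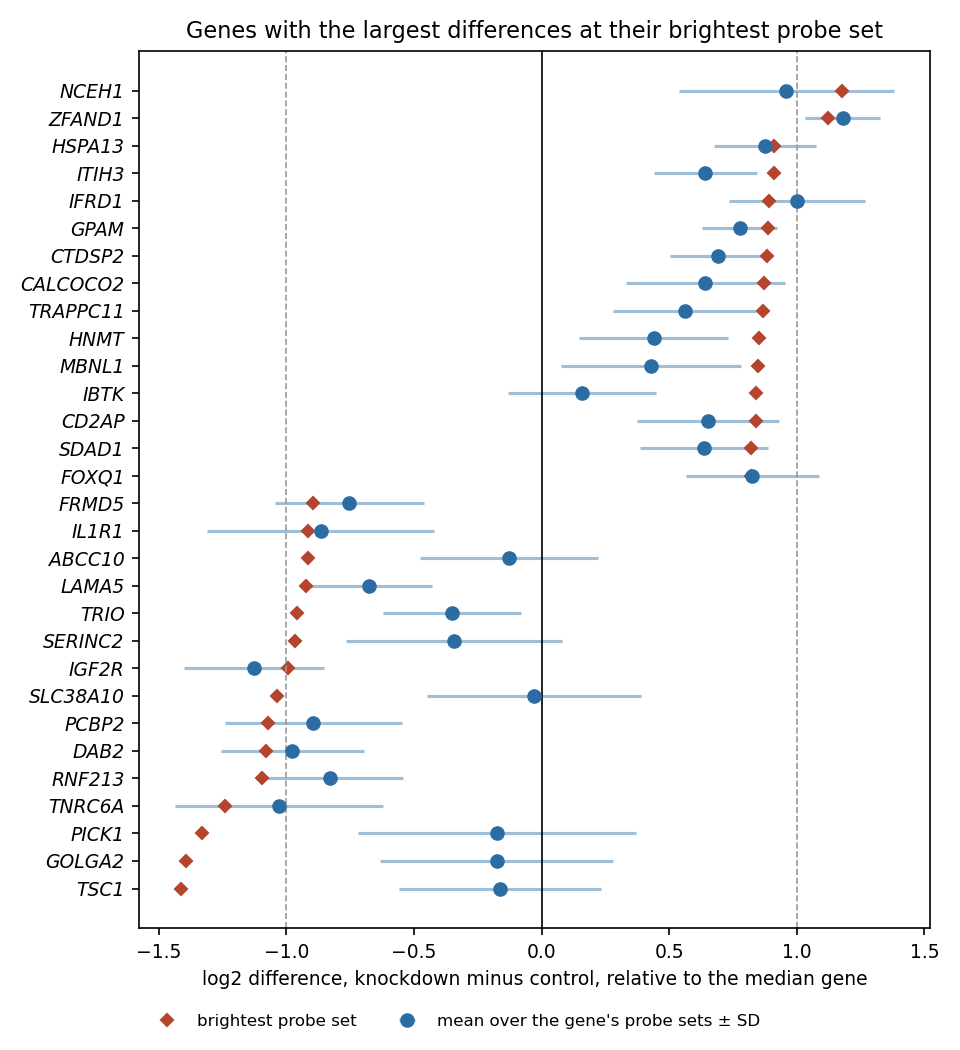
Log2 difference, knockdown minus control, relative to the median gene (horizontal axis) for the 15 genes with the largest increase and the 15 with the largest decrease (vertical axis). Red diamonds are the brightest probe set, blue circles the mean over all probe sets of the gene with bars of 1 SD over probe sets, and dashed lines mark 2-fold. Diamonds and circles lie apart for TSC1, GOLGA2 and PICK1 and close together for ZFAND1, IGF2R and FOXQ1.

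Gene groups fixed in advance were compared next. Of 40 lists, 16 had at least 5 genes at or above the floor. None had a median outside the central 95% of matched random lists, where 0.8 lists would be expected by chance if the lists were independent. The closest at the upper end were the unfolded protein response and the hepatocyte secreted proteins, and at the lower end glycolysis and hypoxia and the splicing factors. The values in this part are medians over genes of the difference at the brightest probe set, relative to the median gene. Beside each median stand its percentile and then the ranges of the list value and of the percentile over the alternative settings, some of which change the genes that enter a list. In deposited values the medians of 15 of the 16 lists lay above 0, the exception being glycolysis and hypoxia at -0.0040. That median turned to 0.12 with means over probe sets and to 0.027 after removal of a gene density trend. In the other direction, S phase and DNA replication went from 0.052 to -0.051 with means over probe sets. Settings that remove the offset between the arrays took further lists below 0. Means over probe sets are given for single genes, also relative to the median gene. A gene mean that lay below the median gene by less than 0.28 was above 0 in deposited values. Probe sets called higher or lower in this part are also placed relative to the median gene. Up to 4 members of a list are given, those with the largest differences at the brightest probe set.

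The unfolded protein response list, genes of endoplasmic reticulum folding and quality control, had a median of 0.20 over 8 genes (percentile 97.4, ranges 0.10 to 0.30 and 78.7 to 99.6), and 7 of the 8 lay above the median gene. With no level floor the median was 0.10 over 9 genes. ATF6, a membrane-bound sensor of this response, was higher by 0.71 ± 0.17 at all of 16 probe sets. HERPUD1 was higher by 0.45 ± 0.19 at all of 12, SEL1L by 0.28 ± 0.24 at 20 of 23 and HYOU1 by 0.13 ± 0.16 at 26 of 30. The related list of amino acid response genes had 4 genes above the floor, too few for a percentile, and all 4 lay above the median gene: the mean of AARS1, an aminoacyl-tRNA synthetase, was 0.39 ± 0.18, that of PSAT1, a serine synthesis enzyme, 0.35 ± 0.30, that of the transporter SLC7A5 0.30 ± 0.25 and that of EPRS1 0.14 ± 0.25. Of the 4 heat shock genes, the collagen chaperone SERPINH1 (-0.58 ± 0.23) and FKBP4 (-0.42 ± 0.18) were lower at every probe set. DNAJA1 (-0.09 ± 0.35) and HSPA4 (-0.01 ± 0.26) lay near the median gene, HSPA4 with 11 of 21 probe sets above it. Apoptosis regulators had a median of 0.23 over 6 genes (percentile 94.0, ranges 0.05 to 0.27 and 60.8 to 99.3), and all 6 lay above the median gene at their brightest probe set. With no level floor the median was 0.05 over 10 genes. The list holds genes of opposite action: MCL1, which opposes apoptosis, was higher by 0.72 ± 0.27 at all of 12 probe sets, and TNFRSF10B, a death receptor, by 0.26 ± 0.24 at 15 of 16. The mean of BIRC2, an inhibitor of apoptosis, was 0.42 ± 0.28, and that of the initiator caspase CASP8 was -0.03 ± 0.27, below the median gene.

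Hepatocyte secreted proteins had a median of 0.13 over 9 genes (percentile 97.0, ranges 0.0067 to 0.15 and 82.1 to 98.3), with 7 of 9 above the median gene. With means over probe sets the median was 0.0067 over 10 genes. ITIH3 was the only member at least 1.5-fold higher. Fibrinogen gamma, FGG, had a mean of 0.27 ± 0.29, while albumin, ALB, with -0.08 ± 0.17, and apolipoprotein B, APOB, with -0.03 ± 0.19, lay near the median gene. Drug and steroid metabolism had 4 genes above the floor, of which the sulfotransferase SULT2A1 was higher by 0.61 ± 0.21 at all of 10 probe sets and the glucuronosyltransferase UGT2B10, which has close paralogs, by 0.28 ± 0.14 at 3. In the same list ALDH1A1 had a mean of 0.16 ± 0.30, and SULT1A1 one of -0.25 ± 0.30 with 7 of 8 probe sets below the median gene. Without a floor the list had a median of 0.34 over 7 genes (percentile 99.4). In the list of gluconeogenesis and urea cycle, the mitochondrial PEP carboxykinase PCK2 had a mean of 0.55 ± 0.19 and the urea cycle enzyme CPS1 one of -0.42 ± 0.32. HGD lay at 0.30 ± 0.24 and ASS1 at -0.08 ± 0.15.

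Fatty acid and triglyceride synthesis had a median of -0.16 over 7 genes (percentile 9.61, ranges -0.16 to -0.025 and 9.61 to 32.1). FASN, the fatty acid synthase, was lower at all of 41 probe sets (mean -0.87 ± 0.19, or 1.83-fold) and ACACA, the acetyl-CoA carboxylase before it in the pathway, at 63 of 64 (-0.55 ± 0.24), while GPAM was higher, as given above, and DGAT2 had a mean of 0.22 ± 0.20. Cholesterol synthesis had a median of -0.05 over 6 genes (percentile 36.1, ranges -0.14 to -0.02 and 8.68 to 40.8), with SQLE at -0.34 ± 0.31 and LSS at -0.40 ± 0.21. In the same list TM7SF2 was higher at all of 8 probe sets (0.21 ± 0.14), and SREBF2 lay at -0.06 ± 0.24. Glycolysis and hypoxia had a median of -0.20 over 7 genes (percentile 2.52, ranges -0.31 to -0.16 and 0.53 to 5.84), with 6 of 7 below the median gene. PGK1, a glycolytic kinase, had a mean of -0.88 ± 0.39, the glucose transporter SLC2A1 -0.50 ± 0.18 with all of 11 probe sets lower, and the hypoxia-induced histone demethylase KDM3A -0.35 ± 0.31. The mean of P4HA2 was -0.14 ± 0.25. Oxidative phosphorylation lay at 0.05 over 7 genes (percentile 62.3, ranges 0.0037 to 0.09 and 55.1 to 73.1), with ATP5F1A at 0.11 ± 0.30, NDUFV1 at 0.0075 ± 0.22, NDUFA10 at -0.07 ± 0.22 and UQCRC1 at -0.15 ± 0.20.

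Proliferation genes lay on both sides of the median gene. The median of S phase and DNA replication was -0.15 over 5 genes (percentile 11.6, ranges -0.33 to -0.10 and 0.52 to 17.2). The replicative helicase subunits MCM3 (-0.63 ± 0.28), MCM5 (-0.38 ± 0.20) and MCM7 (-0.29 ± 0.30) had negative means, and the ribonucleotide reductase subunit RRM2 a positive one (0.26 ± 0.33). Genes of G2/M and mitosis had a median of 0.04 over 8 genes (percentile 46.9, ranges 0.035 to 0.08 and 46.9 to 72.3), with AURKA at 0.21 ± 0.29, BUB1 at 0.20 ± 0.21, CCNB2 at 0.28 ± 0.28 and PLK1 at -0.03 ± 0.22. DNA repair genes had a median of -0.07 over 6 (percentile 24.0, ranges -0.09 to 0.0052 and 23.5 to 51.3), with PRKDC, the DNA-dependent protein kinase, at -0.42 ± 0.25 over 101 probe sets, FANCA at -0.36 ± 0.25, XRCC6 at -0.08 ± 0.12 and PALB2 at 0.14 ± 0.43. MYC targets had a median of 0.08 over 9 genes (percentile 76.5, ranges -0.023 to 0.13 and 39.9 to 89.4) and a mean of -0.02, with SRM, spermidine synthase, at -0.66 ± 0.24, MYBBP1A at -0.42 ± 0.24, NOLC1 at -0.01 ± 0.29 and POLR1B at 0.21 ± 0.30. The 16 ribosomal protein genes had a median of -0.0022 (percentile 23.6, ranges -0.09 to 0.014 and 10.4 to 52.2) and a mean of 0.0088, with 8 above and 8 below the median gene. Their median turned to 0.0078 after quantile normalization and 0.014 after loess. Splicing factors and hnRNPs had a median of -0.15 over 11 genes (percentile 4.68, ranges -0.18 to -0.08 and 1.8 to 14.5), with 8 of 11 below the median gene. The mean of SRSF2 was -0.43 ± 0.34, while HNRNPDL (-0.08 ± 0.23), SF3B1 (-0.07 ± 0.28) and RBM5 (0.09 ± 0.32) lay near the median gene. Of the p53 targets only TNFRSF10B and DDB2 (-0.17 ± 0.23) were above the floor. Without a floor the 9 p53 targets in the table had a median of -0.17 relative to the median gene (percentile 13.3), and with means over probe sets 5 of them had one of -0.0018 (percentile 45.9).

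In the remaining lists with a percentile, signalling by receptor tyrosine kinases and MAPK had a median of -0.04 over 6 genes (percentile 39.5, ranges -0.07 to -0.00045 and 30.5 to 56.7), with the receptor ERBB2 lower at all of 28 probe sets (-0.56 ± 0.19). The means of SOS1 (0.16 ± 0.31), MAPK3 (0.11 ± 0.19) and SHC1 (-0.15 ± 0.30) were smaller. Autophagy and lysosome had a median of 0.02 over 9 genes (percentile 60.5, ranges -0.08 to 0.08 and 29.6 to 74.9) and a mean of -0.08, with ATG9A (-0.57 ± 0.25) and the sterol carrier NPC2 (-0.62 ± 0.20) at the low end. ATG3 (0.20 ± 0.30) and UVRAG (0.15 ± 0.22) each had 12 of 14 probe sets above the median gene. Mesenchymal markers had a median of -0.04 over 5 genes (percentile 34.6, ranges -0.13 to 0.10 and 10.3 to 82.2), which turned to 0.10 after quantile normalization, with the galectin LGALS1 at -0.88 ± 0.14 and the integrin ITGAV at 0.41 ± 0.30. Among lists too short for a percentile, the Wnt feedback ligase RNF43 was below the median gene at all of 12 probe sets (-0.92 ± 0.18). In the same list NKD1 was below it at all of 10 (-0.43 ± 0.27) and DKK1 at 3 of 4 (-0.09 ± 0.23). In deposited values the brightest probe set of NKD1 was 0.19 higher on the knockdown array. The metallothionein MT1X, whose paralogs are nearly identical, was below the median gene at all of 4 (-0.80 ± 0.18). The list of TGF-beta targets and extracellular matrix had 4 genes at the floor, 2 above and 2 below the median gene at their brightest probe set, with means of 0.18 ± 0.15 for THBS1, -0.11 ± 0.16 for FN1, -0.21 ± 0.22 for ITGA2 and -0.23 ± 0.23 for LAMB1. Without a floor its median was -0.12 over 7 genes (percentile 9.2), and with means over probe sets -0.17 over 5 (percentile 7.8). No gene above the floor in the short lists of bile acids, fatty acid oxidation, fetal liver markers, oxidative stress, NF-kB and inflammation, acute phase proteins and epithelial junctions differed by 1.5-fold from the median gene. Without a floor, medians were -0.16 over 5 fetal liver markers (percentile 12.3), -0.10 over 8 bile acid genes (29.6) and -0.017 over 6 genes of fatty acid oxidation (57.9). They were -0.039 over 5 genes of gluconeogenesis and urea cycle (42.0), -0.15 over 5 heat shock genes (18.0) and -0.25 over 5 genes of epithelial junctions (11.6). The interferon-stimulated gene MX2 had a mean of 0.14 ± 0.36. Markers of other liver cells were few. The biliary and epithelial annexin ANXA4 was lower at all of 13 probe sets (-1.19 ± 0.38), CD24 at 6 of 7 (-0.25 ± 0.23) and SPP1 at 4 of 10 (-0.03 ± 0.27), the stellate cell marker ACTA2 had a mean of 0.05 ± 0.20, 1 of 20 endothelial markers was in the table but below the floor, and 0 of 22 leukocyte markers were in it.

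**Figure D3:**
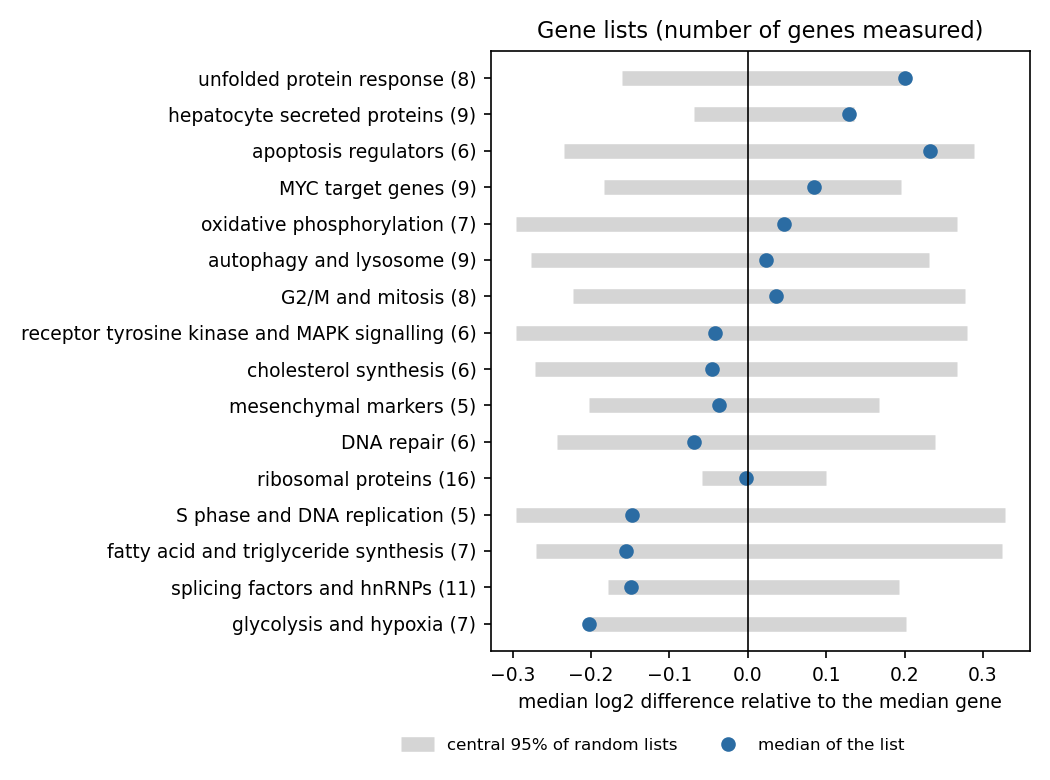
Median log2 difference, knockdown minus control, relative to the median gene (horizontal axis) for the 16 gene lists with at least 5 measured genes (vertical axis, number of genes in parentheses). Blue points are list medians at the brightest probe sets, and grey bars span the central 95% of 10000 random lists matched on size and mean intensity. All 16 points lie within their bars, with glycolysis and hypoxia at the lower edge and the unfolded protein response near the upper edge.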

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

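The table holds 1570 probe sets with no gene name, which no comparison of genes or gene lists above used. Of these, 7 were at least 2-fold higher on the knockdown array relative to the median probe set. Their share, 0.446%, was below that of named probe sets, 0.780%, so the higher side does not stand out. At least 2-fold lower were 35, a share of 2.23% against 1.01% of named probe sets, and this difference was not tested. No biological explanation was tested.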

How the results depend on the processing

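Centring of the means over probe sets and removal of the gene density trend were chosen after seeing the data. No paired analysis was possible because each condition has 1 array, and for the same reason no replicate could be left out. Counts at 2-fold, 17 higher and 4 lower in deposited values, depended on most choices. They were 54 and 9 with no level floor, 7 and 0 with the floor at the 75th percentile, 141 and 26 at 1.5-fold, and 0 and 0 at 3-fold. They were 2 and 8 after median centring and after loess, and 2 and 9 after quantile normalization, because each removes the offset between the arrays. Means over probe sets gave 14 and 0 in deposited values, and 3 and 4 when centred. With means the level floor also rests on the mean level of a gene, so 2 choices change together, and at the main floor the centred means gave 2 and 4. Those 3 were ZFAND1, IFRD1 and RNF144B and those 4 IGF2R, ANXA4, TFDP1 and TNRC6A, of which RNF144B is below the main floor. Removing the gene density trend gave 12 and 4. With the main setting no list stood apart, and other settings moved lists both toward the limits and away from them. Upper and lower counts were 1 and 1 without a floor (drug and steroid metabolism, glycolysis and hypoxia), 2 and 1 at the 75th percentile floor (unfolded protein response and hepatocyte secreted proteins, splicing factors), 1 and 1 with means over probe sets (apoptosis regulators, S phase), and 3 and 1 with list means (unfolded protein response, hepatocyte secreted proteins and apoptosis regulators, glycolysis and hypoxia). Quantile normalization and loess each gave 0 and 1 (glycolysis and hypoxia), and removing the density trend 2 and 0 (unfolded protein response, hepatocyte secreted proteins). Unmatched random lists gave 0 and 0. Centring also gave 0 and 0, but it shifts every gene alike and cannot change a percentile. In the other direction, without a floor the unfolded protein response went to 0.10 (percentile 78.7) and apoptosis regulators to 0.05 (60.8), and with means over probe sets hepatocyte secreted proteins went to 0.0067 (83.1) and fatty acid synthesis to -0.025 (32.1). PCBP2 stayed lower under each alternative run, from -0.61 as the mean over probe sets to -1.08 after quantile normalization. With means over probe sets the deposited differences changed sign for ABCC10 (0.16), GOLGA2 (0.11), PICK1 (0.11), SLC38A10 (0.25) and TSC1 (0.12), since their other probe sets did not share the value of the brightest. Of 180 alternative values of the 30 genes at the extremes, 5 changed sign and 140 stayed within 1 SD over probe sets. All 5 sign changes came with means over probe sets in deposited values. That setting also moved HNMT, IBTK, LAMA5, RNF213, SERINC2 and TRIO by more than 1 SD. Quantile normalization, centring, loess and removal of the density trend shift most genes nearly alike, so the pooled tally says little about agreement between probe sets. Of 103 alternative list medians, 82 stayed within the bootstrap interval over members. These intervals rest on few genes and are wide, so a median inside its interval is no sign of a stable result. For S phase and DNA replication the interval was -0.31 to 0.57 in deposited values. With means over probe sets its median of -0.051 lay inside, although its percentile was 0.52. Both tallies set the alternatives against main values on the deposited scale. Removal of the offset by quantile normalization, centring or loess can therefore count as a move by itself. Under centring the G2/M median counted as moved, although it was 0.035 relative to the median gene in both settings. The table gave no background or detection values. The SD of the difference was 0.41 in the dimmest 10% of probe sets and 0.32 in the brightest.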

Other observations

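The selection of genes by agreement of their probe sets, the tests of scatter and of a single probe set for PCBP2, and the test of an additive offset were chosen after the values had been seen. Of 2742 genes with at least 4 probe sets, 57 were higher by at least 1.5-fold in the mean with every probe set above the median gene, and 84 were lower with every probe set below. At or above the level floor were 24 of the higher and 27 of the lower genes. Among the 10 highest means of these 24, genes not described above were AJUBA, a LIM-domain protein of cell junctions (0.81 ± 0.25 log2, SD over 12 probe sets), and the palmitoyltransferase ZDHHC9 (0.78 ± 0.31 over 16). Among the 10 lowest means of these 27 were TFDP1, the partner of E2F factors (-1.11 ± 0.34 over 11), and the tubulin TUBA1A, which has close paralogs (-0.93 ± 0.72 over 5).

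The other 33 higher and 57 lower genes were below the floor, and their differences do not show that the genes were expressed. The lowest mean of the 2742 genes was that of cyclin D2, CCND2 (-1.46 ± 0.30 over 7 probe sets), whose brightest probe set had a log2 intensity of 8.29, below the median probe set of either array, 8.99 in the knockdown and 8.72 in the control. The next lowest below the floor were IGKV1-5 (-1.45 ± 0.52 over 4, brightest at 8.98), TEAD2 (-1.13 ± 0.29 over 9, brightest at 9.63), IGKC (-1.12 ± 0.48 over 4, brightest at 9.36) and MMP3 (-1.05 ± 0.44 over 7, brightest at 8.24). The highest below the floor were TMEM30A (1.17 ± 0.34 over 11, brightest at 9.72), SNAPC1 (1.15 ± 0.25 over 8, brightest at 9.79), TMEM19 (1.15 ± 0.20 over 7, brightest at 9.18), RNF144B (1.13 ± 0.29 over 16, brightest at 10.09) and RORA (1.10 ± 0.27 over 10, brightest at 8.79). No enrichment was tested.

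PCBP2 was lower on the knockdown array. A mean as low was found for 0.729% of genes with at least 4 probe sets, but with 1 array per condition this cannot be told apart from scatter between cultures. A single aberrant probe set is argued against, since the median over its probe sets was -0.99 relative to the median gene. After a trend with local gene density was subtracted, the mean of PCBP2 was still at -0.84, against -0.89 before. At -0.042 (log2) per doubling of gene density, the trend was too shallow to account for a difference of this size. The subtraction is therefore no check on other technical sources. A hypothesis is that an LNA against a transcript inside PCBP2 may also lower the RNA of the host gene, but this, an effect of TUC338 loss on PCBP2, an off-target match of the LNA and a difference between the 2 cultures were not tested and remain open.

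Most genes were higher on the knockdown array. A fixed additive difference in intensity, as from background, predicts an offset of only 0.02 (log2) in the brightest 10% of probe sets. The observed median there was 0.20, against 0.31 in the dimmest 10%, which argues against it as the only source. The standard error of 0.0061 for the brightest 10% treats probe sets as independent and holds no error between arrays or cultures. An additive part beside other sources, a proportional part, from labelling, normalization or the choice of genes in the table, and a true general increase remain open. No biological explanation was tested.

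Differences between genes on these 2 arrays followed the gene density of the genome around them. Spearman's rho between the mean difference and the number of protein-coding genes within a window of 1000000 bases was -0.15 across 2728 genes (Pearson r = -0.14), with a two-sided permutation p of 1e-05, the smallest that 100000 permutations can give. Genes are not independent replicates, and the trend held 2.13% of the variance of the ranks. Given genomic length the partial rho was -0.15, which argues against gene length as its source, and rho was negative within 19 of 23 chromosomes. The median went from 0.05 in the 731 genes of lowest density to -0.05 in those of highest density (log2, relative to the median gene). Since gene density tracks base composition, a candidate explanation is a composition bias between the labelled samples. Base composition itself was not analysed here. The trend was also not examined at matched intensity. The median difference fell with intensity, from 0.31 in the dimmest 10% of probe sets to 0.20 in the brightest. A dependence on intensity and a biological source of the trend therefore stay open.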
